A study of Mus musculus with 16 samples.

How the data were processed

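Expression was measured by sequencing of polyadenylated RNA in 16 libraries of mouse C3H10T1/2 cells, 2 for each of 8 histone transgenes. The deposited table holds a signal for 20325 genes per library. Per the labels the authors estimated gene counts with RSEM 1.2.4 on mm9, and the file names give a median normalization; aligner, annotation and filters are not stated. In each library the values were multiples of a hundredth of a fixed step, so they are expected counts times 1 constant per library. Values within 0.01 reads of a whole read made up 41.5% to 47.6% of the values above 0, so whole counts could not be recovered, and the 2 planned count-model tests were not run. The step gives an estimated depth of 26.02 to 49.1 M reads per library and a floor of 3 reads of 2.27 to 3.74 in the deposited unit. Intervals and floors cover counting error only. A second table holds the same values for 180 genes.

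Values were tested as log2(value + 1) for the 12670 genes with a mean of at least 10 over the libraries. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust, statmod 1.5.0) was fitted to all groups at once, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The 2 H3.3 wild-type libraries were averaged to 1 sample because they differed by no more than sampling noise over the 2770 genes with whole reads (chi-square p = 0.945), though by more over all 12462 genes (chi-square p = 6.1e-63), leaving 15 samples and 7 residual degrees of freedom. The design set before the data were examined counted them separately. Pair agreement was tested by a chi-square on genes with at least 20 reads, all of them and those with whole reads in both libraries of a pair. Tests covered 11 comparisons between groups and 2 interactions. No pairing by replicate number was seen: over 28 pairs of groups the correlation of replicate differences ran from -0.265 to 0.0598. In 5 groups the libraries were so close that their differences could hardly show a pairing, so most of these correlations decide little. A replicate block is given only as an alternative.

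Of 38 gene lists written before the data were examined, 36 had at least 5 tested members. They were tested with camera at a correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. fry asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. Genes named were chosen by a rule fixed before the data were examined. In the first 6 comparisons and the interactions these are the 10 largest changes each way among genes called, with a mean of at least 50 in a compared group and, outside the interactions, no overlap between the libraries of the groups; in the other comparisons the 5 largest each way. Up to 4 members of a list told and 19 fixed genes are added, and provisional symbols are left out; some genes that the rule named are not reported here. The genes and lists drawn in the plots, Mtap, and Adipoq and Mest where so marked were picked after their values were seen. For genes at 0 in a group a lower bound against the floor is given, and for 1 to 3 reads a ratio with its 95% counting interval.

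Overlaps of lists were set beside independent lists and 20 simulated data sets of unchanged groups and 20 more, chosen after the data were seen, in which close pairs share a culture, and medians beside 10000 random lists matched in 20 bins of expression. The test was checked on simulated data of 12670 genes for H3.3 G34W against H3.3 wild type with known changes. It recovered 33.0% of 2-fold, 78.8% of 4-fold and 90.1% of 8-fold changes with a mean of 8.95 false calls; with close pairs counted as 1 sample it recovered 13.7%, 71.8% and 87.8% of these. All libraries varied independently in this check, so its pairs were not close as in the data. Where close pairs shared a culture, the same test made a mean of 421 false calls. Alternatives were other pseudocounts (0.5 and 5), no filter and a minimum mean of 50, a TMM rescaling, quantile normalization, eBayes without trend and robust, a fit of the compared groups alone, a replicate block, and leaving out each library. The averaging of the wild-type libraries was chosen after the data were seen, so their separate count, the one of the design, is listed among the alternatives. Each of the 5 close pairs counted as 1 sample was added after the data were seen. Where a group is left with 1 library, that library is assumed to vary like the other groups. No libraries were left out of the main fit.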

Results

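The data are gene expression values of C3H10T1/2 cells, a mouse line of mesenchymal stem cell type, that stably expressed a histone H3 transgene. After transduction for 2 days the cells were selected with puromycin at 1.5 µg/ml for 4 days, and polyadenylated RNA was sequenced. The 8 groups of 2 libraries each expressed H3.3 wild type, H3.3 with G34W, G34R or K27R, H3.3 with G34W and K27R or with G34W and K36R on the same tail, H3.1 wild type, or H3.1 with G34W. Each change is named by the residue of the wild type, its position in H3 and the residue that replaced it. The series asks how changes at residue 34 of H3.3 alter transcription in these cells. The 16 libraries held an estimated 26.02 to 49.1 M reads, and between 14275 and 15261 of the 20325 genes in the table were above 0. Depth was 34.8 to 49.1 M reads in the 6 libraries of H3.1 wild type, H3.1 G34W and H3.3 G34W K36R, and 26.02 to 33.8 M in the other 10. Values below are the deposited values, given as mean ± SD (n = 2 libraries). H3.3 wild type counts as 1 sample and has a mean without SD. Log2 fold changes carry the SE of the fit. Coordinates are not given, since the table of values carries none.

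The libraries of a group were close to each other to very different degrees. The H3.3 wild-type pair differed by no more than sampling noise over the 2770 genes with whole reads (chi-square per degree of freedom 0.957, p = 0.945) and was therefore averaged and counted as 1 sample. Over all 12462 genes, fractional estimates included, it differed by more than sampling noise (chi-square per degree of freedom 1.23, p = 6.1e-63), and the SD of the log2 ratio over genes with at least 1000 reads was 0.119, against 0.067 to 0.084 in the 4 other close pairs. The design set before the data were examined counted these libraries separately, and those counts stand beside the others below where they differ by over 1.5 times. The pairs of G34R, K27R, G34W K27R and G34W K36R differed by more than sampling noise, with 1.17 to 1.36 per degree of freedom over genes with whole reads and, over all genes, 5.79, 3.14, 2.82 and 1.75. Those of H3.3 G34W, H3.1 wild type and H3.1 G34W reached 48.0, 32.5 and 43.3 over genes with whole reads and 260.1, 225.5 and 214.5 over all genes. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. In the principal components the first axis (51.3% of the variance) set H3.1 wild type, H3.1 G34W and H3.3 G34W K36R apart from the other groups, and the second (17.2%) set H3.3 G34W K27R apart. Replicate 1 of H3.1 G34W correlated with replicate 1 of H3.1 wild type at 0.992 across genes, above the 0.969 with its own replicate, and replicate 2 of H3.1 G34W lay nearest to replicate 2 of H3.3 G34W K36R (0.975). Both H3.3 G34W libraries lay nearest to a G34R library (0.949 and 0.978, against 0.938 with each other). Genes are not independent replicates in these correlations.

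**Figure D1:**
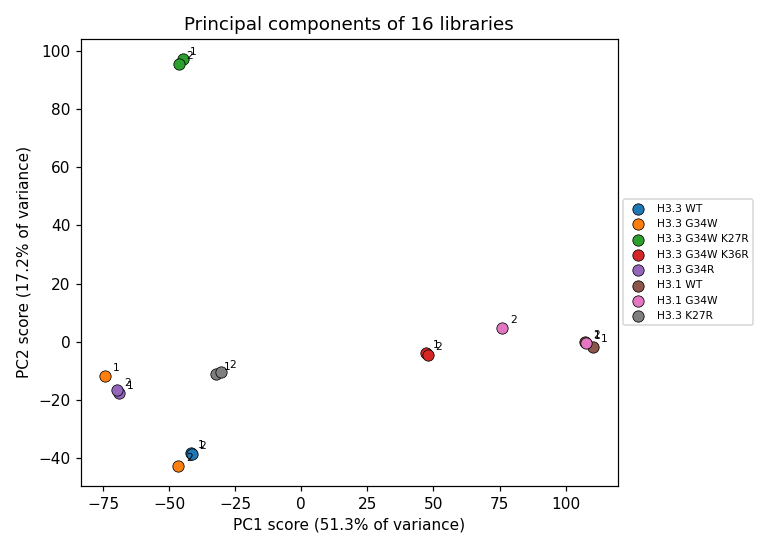
Scores of the 16 libraries on the first 2 principal components of the log2 values, with the replicate number beside each point and the group in colour. The first axis holds 51.3% of the variance and the second 17.2%; the H3.1 groups and H3.3 G34W K36R lie on the right.

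Counts of genes called (limma, adjusted p under 0.05, 12670 genes) depended on how the close pairs were counted. With each of the 5 close pairs counted as 1 sample, an alternative chosen after the data were seen, calls ended altogether in H3.3 G34W, G34R and K27R against wild type, G34W K27R against K27R, G34R against G34W and the interaction of G34W with the histone type. H3.1 G34W had none in either count. Data were also simulated with no change by group, cultures that varied as the 3 differing pairs do and close pairs that shared a culture. The same test then called a mean of 421 genes between H3.3 G34W and H3.3 wild type and 2226 between H3.3 G34W K27R and H3.3 K27R, and a mean of at most 0.05 with close pairs counted as 1. In this simulation the mean was above the observed count for G34W, G34R and K27R against wild type, H3.1 G34W, G34R against G34W and both interactions, so calls there cannot be set apart from differences between single cultures. The plot of counts gives these 3 values for each comparison.

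**Figure D2:**
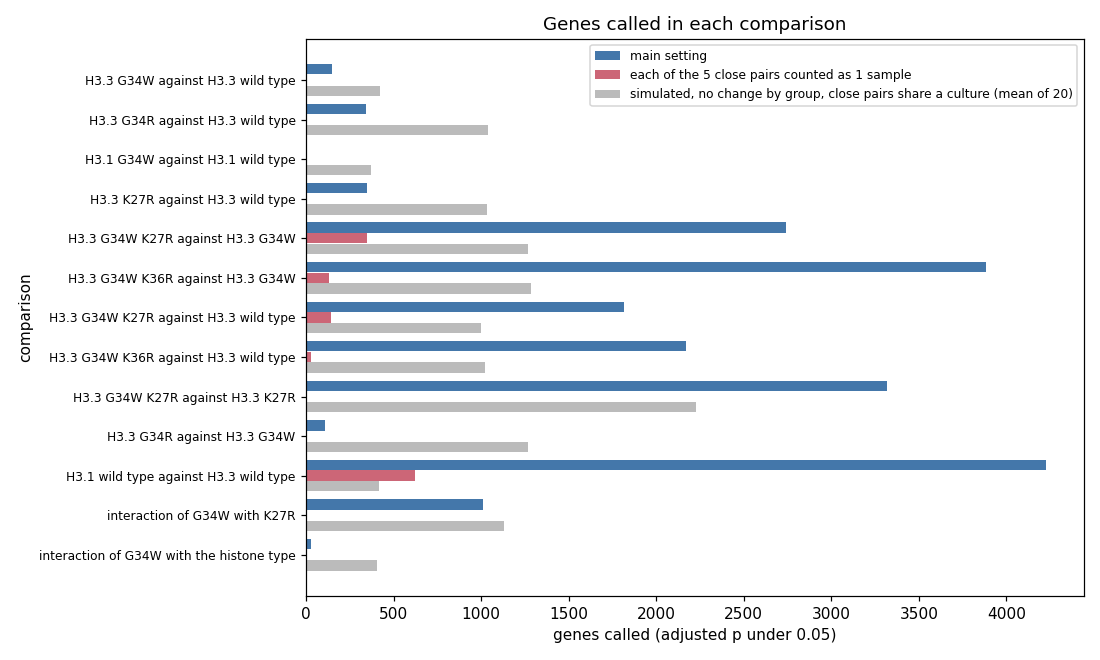
Number of genes called in each comparison in the main setting, with each of the 5 close pairs counted as 1 sample, and as the mean of 20 simulated data sets with no change by group in which close pairs share a culture. H3.1 against H3.3 wild type had 4229 calls, 621 and a simulated mean of 414.

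H3.3 G34W was compared with H3.3 wild type. Mest, an imprinted gene of the hydrolase family, was at 4912 ± 456 against 90.5 (log2 fold change 5.74 ± 0.49, adjusted p = 7.3e-04). Serpina3g, a serine protease inhibitor, was at 7.27 ± 3.65 against 1977 and the chemokine gene Ccl2 at 136 ± 3.23 against 7077 (log2 fold change -5.69 ± 0.46). Cdkn2b, which encodes the cell cycle inhibitor p15, was at 53.4 ± 12.1 against 0 (at least 18.4-fold higher, floor of 3 reads per library), and Cdkn2a, which encodes p16 and Arf, at 38.5 ± 1.29 against 0.484 (ratio 79.5, 95% counting interval 13.8 to 3172). In all 150 genes were called, 95 higher and 55 lower. The other genes named by the rule on the higher side were Robo1, Btn1a1, Podxl2, Igfbp2 (log2 fold change 4.55 ± 0.55), Shank3, Chst8, Entpd2 and Pcsk5. On the lower side they were Serpina3f (log2 fold change -7.11 ± 0.46), Serpina3i, Csmd1, Cxcl5, Prl2c3, Prl2c2, Gabra3 and Mt2, a metallothionein (82.2 ± 53.9 against 1790.0). Robo1, a guidance receptor, was at 187 ± 93.7 against 0.969 (ratio 193, 95% counting interval 51.7 to 1561).

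Of 22 inflammatory cytokine and NF-kB response genes 3 fell and none rose in H3.3 G34W, and 11 fell when adjusted over the list alone (median log2 fold change -1.25; adjusted p = 6.2e-09 by camera and adjusted p = 0.0185 with an estimated correlation). Ccl2, Ccl7 (53.6 ± 26.4 against 1089.9) and Cxcl5 (493 ± 610.0 against 16095) fell, and Nfkbia was at 1426 ± 396 against 3266 with an adjusted p of 0.0554. This list and the interferon-stimulated genes of G34R against G34W gave the 2 list calls, of 130 in all comparisons, that hold with an estimated correlation. Among the other lists called, Cdkn2a and Cdkn2b were the members that rose of the 6 Ink4, Arf and Cip/Kip inhibitors (adjusted p = 0.00148 by camera and adjusted p = 0.335 with an estimated correlation). Of 44 collagens and matrix proteins, Mfap5, Fbln5 and Col5a3 rose and Efemp1 fell (median log2 fold change 0.42; adjusted p = 0.00887 by camera and adjusted p = 0.335 with an estimated correlation). The 21 genes of cholesterol synthesis had a median log2 fold change of 0.98 with no member called (adjusted p = 4.0e-08 by camera and adjusted p = 0.358 with an estimated correlation). The 39 ribosomal protein genes had one of -0.71 with none called (adjusted p = 4.8e-14 by camera and adjusted p = 0.358 with an estimated correlation). Of 19 adipocyte genes none was called (median log2 fold change 1.16; adjusted p = 0.0120 by camera and adjusted p = 0.583 with an estimated correlation); Adipoq, picked after its values were seen, was at 4082 in replicate 1 of G34W and 7.65 in replicate 2. Hey1 was the called member of the 14 Notch and Hedgehog genes (1066 ± 329 against 321; adjusted p = 0.0477 by camera and adjusted p = 0.358 with an estimated correlation).

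The 150 calls fell to 0 with close pairs counted as 1 sample, when the adjusted p of Mest was 0.0716 and that of Serpina3g, Serpina3f and Ccl2 0.0540. It was 956 with both wild-type libraries counted separately. Leaving out 1 library gave 331 and 1526 without H3.3 G34W replicates 1 and 2, 58 and 59 without H3.3 G34W K27R replicates 1 and 2, 54 and 54 without H3.3 G34W K36R replicates 1 and 2, 59 and 56 without H3.3 G34R replicates 1 and 2, 316 and 316 without H3.1 wild type replicates 1 and 2, 431 and 430 without H3.1 G34W replicates 1 and 2 and 50 and 50 without H3.3 K27R replicates 1 and 2.

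H3.3 G34R, a second substitution at the same residue, was compared with the same wild type. Eln, which encodes elastin, was at 322520.0 ± 5289.5 against 39425 (log2 fold change 3.03 ± 0.40), and H3f3b, a gene of H3.3, at 53513 ± 1152 against 25528 (log2 fold change 1.07 ± 0.19, adjusted p = 0.0174). Whether reads of the H3.3 transgene were counted under H3f3b was not tested. Of 49 interferon-stimulated genes 16 rose and none fell, and 36 rose when adjusted over the list alone (median log2 fold change 2.10, 1.90 with the members near 0 at their bound; adjusted p = 2.9e-29 by camera and adjusted p = 0.200 with an estimated correlation). Mx1, an antiviral GTPase, was at 468 ± 38.4 against 10.5, and Gbp3 at 730.1 ± 118 against 111. Of the 22 inflammatory genes 4 fell (10 adjusted over the list alone; adjusted p = 1.9e-06 by camera and adjusted p = 0.0563 with an estimated correlation), namely Ccl7, Ccl2 (660.0 ± 134 against 7077), Cxcl5 and Cxcl1 (265 ± 38.2 against 5579.6). Of 21 immediate early genes 3 rose, Klf2, Egr2 (999 ± 46.1 against 62.5) and Jun, and 11 when adjusted over the list alone (adjusted p = 2.5e-07 by camera and adjusted p = 0.200 with an estimated correlation). Sc5d was the called member of the cholesterol synthesis genes (12 of 21 adjusted over the list alone; adjusted p = 2.3e-11 by camera and adjusted p = 0.337 with an estimated correlation). Eln, Fbln5, Col5a3 and Mfap5 rose among the 44 matrix genes (adjusted p = 0.0188 by camera and adjusted p = 0.283 with an estimated correlation). In all 344 genes were called, 222 higher and 122 lower. The rule named Rsad2, Cdkn2b, Cxcl9, Cmpk2, Cdkn2a, Robo1, Arhgef5, Oas1g, Tinag and Trim30d as higher, each at a mean of 3 or fewer reads per library in wild type. Cdkn2b was at 165 ± 5.25 against 0 (at least 56.9-fold higher) and Cdkn2a at 141 ± 2.38 against 0.484 (ratio 291, 95% counting interval 51.7 to 11525). As lower it named Cxcl5, Serpina3i, Csmd1, Prl2c3, Serpina3g (log2 fold change -5.94 ± 0.63), Vnn1, Cxcl1, Raet1d, Tspan7 (log2 fold change -4.01 ± 0.47) and Serpina3f. The count was 0 with close pairs counted as 1 sample and 1313 with the wild-type libraries counted separately. It was 986 and 987 without H3.3 G34W replicates 1 and 2, 188 and 188 without H3.3 G34W K27R replicates 1 and 2, 189 and 189 without H3.3 G34W K36R replicates 1 and 2, 92 and 75 without H3.3 G34R replicates 1 and 2, 600 and 598 without H3.1 wild type replicates 1 and 2, 708 and 712 without H3.1 G34W replicates 1 and 2 and 174 and 174 without H3.3 K27R replicates 1 and 2.

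The lists of G34W and G34R against wild type shared 71 of the genes called higher and 36 of those called lower, and none was called in opposite directions. Independent lists of these sizes would share 1.66 and 0.530, and simulated unchanged groups without shared cultures shared 0 (covariance of the fold changes across genes 0.129). The simulated data with no change by group and close pairs that shared a culture had means of 104.5 and 105.05 shared genes. Overlap thus arises there with no common effect. The simulated lists were longer, with means of 421 and 1040 calls against 150 and 344, so the counts of shared genes cannot decide on a common effect. The same holds for K27R below (1034 against 349 calls). The fold changes had a covariance across genes of 0.430, against a mean of 0.344 and a highest value of 0.381 in this simulation. Genes varied independently in each simulated culture, so these covariances spread less than where genes move together. They cannot decide on a common effect either. K27R against the same wild type shared 29 higher and 13 lower genes with G34W (simulated means 106.2 and 102.75) and 86 and 24 with G34R (165.25 and 164.65), with covariances of 0.172 and 0.320 (0.342 and 0.343). In the direct comparison of G34R with G34W 107 genes were called, 92 higher in G34R and 15 lower. Of 49 interferon-stimulated genes 23 were higher in G34R and 47 when adjusted over the list alone (median log2 fold change 2.48; adjusted p = 8.4e-77 by camera and adjusted p = 0.0315 with an estimated correlation), among them Gbp2 (825 ± 113 against 86.4 ± 18.5), Herc6 (585 ± 58.3 against 152 ± 42.9), Ifi204 and Ccl5. The rule named Rsad2 (343 ± 47.9 against 9.84 ± 13.9), Gbp8, Cmpk2, Ifi205 and Zbp1 as higher. As lower it named Tmem117, Npr3 (1489 ± 63.9 against 7241 ± 1302), Slc1a6, Ezr and Aldh1a7. Cdkn2a was at 141 ± 2.38 against 38.5 ± 1.29. Klf2 was the called member of the immediate early genes (adjusted p = 1.9e-12 by camera and adjusted p = 0.185 with an estimated correlation). The shift of this list rested on replicate 2 of G34W, by list medians of log2 values minus each gene's mean over all libraries. The median was -0.95 in replicate 2 and 1.08 in replicate 1, against 1.02 and 1.18 in G34R. The count was 0 with close pairs counted as 1 sample. Leaving out 1 library gave 207 and 1065 without H3.3 G34W replicates 1 and 2, 70 and 70 without H3.3 G34W K27R replicates 1 and 2, 14 and 3 without H3.3 G34R replicates 1 and 2 and 183 and 182 without H3.1 G34W replicates 1 and 2.

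H3.1 G34W against H3.1 wild type asks the same of the replication-dependent histone and shares no library with the comparisons above. limma called 0 of 12670 genes, with 2015 at an unadjusted p under 0.05. Mest, picked after its values were seen, was at 225.9 and 731 in the H3.1 G34W libraries and 125.1 in both of H3.1 wild type. Lists with a camera call included the 27 S phase genes (median log2 fold change -0.81; adjusted p = 7.6e-09 by camera and adjusted p = 0.608 with an estimated correlation) and the interferon-stimulated genes (median log2 fold change 0.70, 0.59 with the members near 0 at their bound; adjusted p = 4.4e-05 by camera and adjusted p = 0.608 with an estimated correlation), with no member called. Both shifts rested on replicate 2 of H3.1 G34W, by list medians of log2 values minus each gene's mean over all libraries. The S phase median was -0.66 in replicate 2 and 0.79 in replicate 1, against 0.81 and 0.92 in H3.1 wild type. The interferon median was -1.06 in replicate 2, while replicate 1 lay between the H3.1 wild-type libraries (-3.12 and -2.93). The count was 4 with the H3.3 wild-type libraries counted separately, and 13 and 13 without H3.3 G34W replicates 1 and 2, 2267 without H3.1 wild type replicate 1 and 2477 and 1 without H3.1 G34W replicates 1 and 2. Replicates 1 of these H3.1 groups are the libraries that lie nearest to each other. The 95 genes higher in H3.3 G34W had a median log2 fold change of 0.15 here (0.12 with genes near 0 at their bound), at percentile 98.2 of 10000 expression-matched random lists, and the 55 lower genes one of -0.10, at percentile 3.62. The sign was shared by 66 of the 95 and 32 of the 55.

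H3.3 K27R, with the lysine change alone, was compared with H3.3 wild type. Of 49 interferon-stimulated genes 23 rose and none fell, 46 when adjusted over the list alone (median log2 fold change 2.30, 2.28 with the members near 0 at their bound; adjusted p = 4.3e-38 by camera and adjusted p = 0.219 with an estimated correlation). Mx1 was at 430.5 ± 3.79 against 10.5 and Oas1a at 1318 ± 12.9 against 48.3. Chondrocyte genes went both ways (adjusted p = 0.0130 by camera and adjusted p = 0.689 with an estimated correlation). Sox9, a transcription factor of cartilage, fell to 4582 ± 156 against 9385, and Hapln1 was at 4.00 ± 0.363 against 921, while Matn3 and Col10a1 rose. Of 25 glycolysis and hypoxia genes Pdk1, Car9 and Higd1a fell and Pfkp rose (adjusted p = 0.0411 by camera and adjusted p = 0.689 with an estimated correlation). Igfbp2, an insulin-like growth factor binding protein, was at 1407 ± 93.6 against 17.9 (log2 fold change 6.22 ± 0.55), and Lcn2, an iron-scavenging acute phase protein, at 11.8 ± 4.36 against 3768. In all 349 genes were called, 234 higher and 115 lower. The rule also named Rsad2, Oas1g, Cdkn2b, Cmpk2, Kcnmb4, Tinag, Cdkn2a, Arhgef5 and Trim30d as higher, each at a mean of 3 or fewer reads per library in wild type. As lower it also named Csmd1, Cxcl5, Steap4, Sfrp2 (128 ± 3.83 against 4665), Cd24a, C3, Cmtm5 and Tmem176a (log2 fold change -4.71 ± 0.36). The count was 0 with close pairs counted as 1 sample and 1124 with the wild-type libraries counted separately. Without 1 library it was 880 and 882 without H3.3 G34W replicates 1 and 2, 232 without H3.3 G34W K36R replicate 1, 223 and 229 without H3.3 G34R replicates 1 and 2, 531 and 532 without H3.1 wild type replicates 1 and 2, 659 and 657 without H3.1 G34W replicates 1 and 2 and 114 and 101 without H3.3 K27R replicates 1 and 2.

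The double mutant H3.3 G34W K27R was compared with H3.3 G34W, which keeps K27 on the same tail. All 49 interferon-stimulated genes rose (median log2 fold change 5.25, 5.04 with the members near 0 at their bound; adjusted p = 5.4e-47 by camera and adjusted p = 0.127 with an estimated correlation). With close pairs counted as 1 sample 43 of them rose. Ifi204 was at 12168 ± 424 against 508 ± 32.1 (log2 fold change 4.58 ± 0.12), Gbp2 at 7158 ± 119.8 against 86.4 ± 18.5, and Rsad2, which encodes the antiviral enzyme viperin, at 5339.7 ± 114 against 9.84 ± 13.9. All 30 G2 and M phase genes fell (median log2 fold change -3.87; adjusted p = 2.8e-27 by camera and adjusted p = 0.331 with an estimated correlation), 26 of them also with close pairs counted as 1. Ccnb2, a mitotic cyclin, was at 113 ± 1.22 against 2614 ± 885 and Cenpf, a kinetochore protein, at 138 ± 10.1 against 3043 ± 575. Of 27 S phase genes 19 fell (24 adjusted over the list alone; adjusted p = 9.7e-09 by camera and adjusted p = 0.551 with an estimated correlation), with Tk1 at 333 ± 5.78 against 4928 ± 2119.6. Of 21 cholesterol synthesis genes 18 fell (21 adjusted over the list alone; median log2 fold change -1.87; adjusted p = 9.1e-11 by camera and adjusted p = 0.414 with an estimated correlation), such as Idi1 (1481 ± 3.68 against 8494 ± 2429) and Fdft1. Of 22 inflammatory genes 10 rose and 1 fell (adjusted p = 0.00120 by camera and adjusted p = 0.160 with an estimated correlation), with Ccl2 at 13959.6 ± 36.6 against 136 ± 3.23. Chondrocyte genes fell, 8 of 14 (adjusted p = 1.1e-05 by camera and adjusted p = 0.331 with an estimated correlation), such as Matn3 (6.04 ± 3.84 against 316 ± 5.93) and Col9a1. Cdkn2a was at 442 ± 20.9 against 38.5 ± 1.29 and Cdkn2b at 778 ± 26.9 against 53.4 ± 12.1. Ezh2, the catalytic subunit of PRC2, was at 862 ± 56.2 against 1654 ± 495 (log2 fold change -0.91 ± 0.24, adjusted p = 0.0216). In all 2742 genes were called, 1171 higher and 1571 lower.

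The rule named for this comparison Rsad2, Cxcl11, H28, Cxcl10 (2700.0 ± 62.1 against 7.50 ± 7.95), Cmpk2, Gbp8, Ccl5, Zbp1, Oas1g and Oasl2 as higher. As lower it named Fxyd6, Megf6, Scg2, Wfdc12, Serpina1e, Gli1, Cnn1, Panx3 (7.42 ± 3.62 against 457 ± 195), Btn1a1 and Susd5. Cxcl11 was at 559 ± 23.6 against 0 ± 0 (at least 184-fold higher). Against wild type the double mutant had 1815 calls, 813 higher and 1002 lower. All 49 interferon-stimulated genes were higher there (median log2 fold change 4.80; adjusted p = 6.2e-47 by camera and adjusted p = 0.127 with an estimated correlation). All 30 G2 and M phase genes were lower (median log2 fold change -3.89; adjusted p = 2.8e-29 by camera and adjusted p = 0.290 with an estimated correlation). Named there were Rsad2, Cxcl9 (2144 ± 9.82 against 0, at least 738-fold higher), H28, Cdkn2b and Cmpk2 as higher, and Hapln1, Krt14, Lcn2, Mal and Tmem176a (log2 fold change -6.96 ± 0.36) as lower. Igf2, an imprinted growth factor gene, was at 631 ± 42.6 against 43.1. With close pairs counted as 1 sample 347 genes were called against G34W and 141 against wild type, the latter with 80 higher and 61 lower. The count against G34W was 1305 and 1312 without H3.3 G34W K27R replicates 1 and 2. That against wild type was 3499 with the wild-type libraries counted separately, and 2888 and 2888 without H3.3 G34W replicates 1 and 2 and 893 and 892 without H3.3 G34W K27R replicates 1 and 2.

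Against H3.3 K27R the same double mutant differs by G34W where position 27 is arginine. Of 19 adipocyte genes 7 were higher in the double mutant (9 adjusted over the list alone; median log2 fold change 0.98; adjusted p = 0.00192 by camera and adjusted p = 0.631 with an estimated correlation). Cfd, which encodes adipsin, was at 485 ± 27.98 against 0 ± 0 (at least 140.0-fold higher), Adipoq, which encodes adiponectin, at 1323 ± 49.6 against 10.3 ± 0.467, and Cebpa at 828 ± 30.1 against 445 ± 31.2. Interferon-stimulated genes were higher, 41 of 49 (median log2 fold change 2.48; adjusted p = 8.4e-22 by camera and adjusted p = 0.473 with an estimated correlation). All 30 G2 and M phase genes were lower (median log2 fold change -3.79; adjusted p = 6.2e-25 by camera and adjusted p = 0.473 with an estimated correlation). In all 3320 genes were called, 1481 higher and 1839 lower, but more higher than lower with quantile normalization (2068 and 1882). The rule named Cfd, Plin1, Cidec, Adipoq and Kera as higher. As lower it named Serpina1e, Krt14, Gli1, Car6 and Igfbp2 (8.33 ± 0.770 against 1407 ± 93.6). With close pairs counted as 1 sample the count was 0. It was 1459 and 1478 without H3.3 G34W K27R replicates 1 and 2 and 1495 and 1448 without H3.3 K27R replicates 1 and 2.

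The genes called between H3.3 G34W and wild type were followed in comparisons with other libraries. Between the G34W K27R double mutant and K27R, the 95 higher genes had a median log2 fold change of 0.27 (percentile 99.9 of the random lists; 62 of 95 higher), and the 55 lower genes one of -0.13 (percentile 8.67; 28 of 55 lower). Between G34R and K27R, a comparison chosen after the data were seen, the medians were 0.71 and -0.88, with 78 of 95 and 46 of 55 in the direction of G34W. Against H3.3 G34W itself the medians in G34W K27R were -0.60 and 1.22, beside means of -0.41 and 0.44 in simulated unchanged groups with shared cultures (-0.31 and 0.33 without), where the most extreme of 20 were -0.53 and 0.60. In G34W K36R they were -0.60 and 1.42, beside -0.44 and 0.46 (-0.30 and 0.34), the most extreme being -0.54 and 0.65. A list chosen for its difference moves back by chance in a comparison with the same libraries. The observed medians lay outside these 20 simulations, but the simulated lists were matched in number of genes, not in size of change. In the interaction with the histone type, which holds the same difference, medians were 1.53 and -2.42, against simulated means of 1.25 and -1.31. A larger difference moves back further, so a reversal beyond chance cannot be told from these medians.

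H3.3 G34W K36R was compared with H3.3 G34W, from which it differs by K36R on the same tail, but also in depth and on the first principal component. Eln was at 69.8 ± 8.53 against 147560.0 ± 8939 (log2 fold change -11.03 ± 0.33, adjusted p = 1.2e-07, and 6.4e-04 with close pairs counted as 1). Of 14 chondrocyte genes 11 fell (median log2 fold change -3.09; adjusted p = 1.9e-07 by camera and adjusted p = 0.285 with an estimated correlation), such as Col9a1, a cartilage collagen (21.7 ± 9.46 against 3955 ± 2239), Lect1 (3.18 ± 1.73 against 1131 ± 97.9) and Col9a3. Of 44 collagens and matrix proteins 15 fell and 3 rose (adjusted p = 0.0130 by camera and adjusted p = 0.349 with an estimated correlation); Dcn, which encodes decorin, was at 48.6 ± 2.33 against 1792 ± 1286, and Thbs2 rose. Of 31 replication-dependent histone genes 17 fell and 1 rose in polyadenylated RNA (adjusted p = 8.2e-06 by camera and adjusted p = 0.285 with an estimated correlation), with Hist1h3d at 285 ± 52.5 against 4600.4 ± 1571 and Hist1h2ao at 4733 ± 229 against 23.0 ± 3.25. Since only polyadenylated RNA was sequenced, the total RNA of these genes is not known. Of 14 smooth muscle and myofibroblast genes 8 rose (adjusted p = 0.0130 by camera and adjusted p = 0.733 with an estimated correlation), such as Itga8 and Tpm2. Of 19 adipocyte genes 5 fell (adjusted p = 0.00570 by camera and adjusted p = 0.7499 with an estimated correlation), with Cebpa at 152 ± 30.8 against 1810.1 ± 202. Of 30 nuclear genes of oxidative phosphorylation 12 fell (adjusted p = 1.0e-04 by camera and adjusted p = 0.7499 with an estimated correlation), such as Cox7a2. Suz12, a PRC2 subunit, was at 4403 ± 41.9 against 1933 ± 458 (log2 fold change 1.21 ± 0.20). Nsd1, a methyltransferase for K36, was at 6607 ± 75.6 against 3305 ± 371, and Col1a1 at 346115 ± 5375 against 117339 ± 99399.9. In all 3882 genes were called, 1827 higher and 2055 lower, but more higher than lower with the TMM rescaling (1932 and 1906) and quantile normalization (2180 and 1977). The rule named, among others, Hist1h2ao, Serpina3g (864 ± 14.1 against 7.27 ± 3.65), Itih2, Tceal3, Pkp2 (704 ± 32.8 against 9.38 ± 5.30), P2ry1, Ptchd1, Theg and Hdx as higher. As lower it named Eln, Olfm2, Fxyd6, Lect1, Pcsk5, Cmtm5, Col9a1, Bmx (3.33 ± 2.21 against 621 ± 260.1), Adamts15 and G0s2.

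Against wild type G34W K36R had 2169 calls, 1051 higher and 1118 lower, but more higher than lower with the TMM rescaling (1091 and 1067) and quantile normalization (1239 and 1197). Of 15 imprinted genes 6 rose and none fell (median log2 fold change 0.68; adjusted p = 3.2e-04 by camera and adjusted p = 0.120 with an estimated correlation), among them Mest (2379 ± 19.9 against 90.5), Igf2 (1554 ± 2.82 against 43.1), Ndn and Dlk1. Of 21 cholesterol synthesis genes 16 rose (median log2 fold change 1.72; adjusted p = 7.6e-11 by camera and adjusted p = 0.743 with an estimated correlation), such as Sc4mol and Idi1 (23553 ± 147 against 4468). Named there were Arhgef5 (1441 ± 20.2 against 0, at least 496-fold higher), Hist1h2ao, Chodl, Tceal3 and Itga8 as higher, and Lect1, Eln, Hapln1, Mal and Krt14 as lower. With close pairs counted as 1 sample 132 genes were called against G34W and 27 against wild type. Against G34W the count was 1720 and 1645 without H3.3 G34W K36R replicates 1 and 2. Against wild type it was 4256 with the wild-type libraries counted separately, and 3320 and 3319 without H3.3 G34W replicates 1 and 2, 814 and 806 without H3.3 G34W K36R replicates 1 and 2 and 3302 and 3300 without H3.1 wild type replicates 1 and 2.

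H3.1 wild type against H3.3 wild type compares the control transgenes, and these groups also differed in depth and on the first principal component. Lect1 was at 0 ± 0 against 3227 (at least 1239.7-fold lower) and Eln at 11.7 ± 2.74 against 39425. Of 14 chondrocyte genes 11 were lower (median log2 fold change -4.12; adjusted p = 3.4e-08 by camera and adjusted p = 0.341 with an estimated correlation), 9 of them also with close pairs counted as 1 sample. Of 44 collagens and matrix proteins 20 were lower and 5 higher (adjusted p = 9.9e-04 by camera and adjusted p = 0.341 with an estimated correlation), with Col6a2 at 1087 ± 325 against 35645. Of 49 interferon-stimulated genes 29 were lower and 3 higher (median log2 fold change -2.14, -2.13 with the members near 0 at their bound; adjusted p = 2.3e-06 by camera and adjusted p = 0.672 with an estimated correlation), with Tap1 at 41.2 ± 2.51 against 524 and Ifi204 at 1778 ± 159.6 against 914. Of 21 Wnt genes 9 were lower and 2 higher (adjusted p = 0.0210 by camera and adjusted p = 0.398 with an estimated correlation), such as Sfrp2 (4.88 ± 2.75 against 4665) and Rspo3. Of 14 Notch and Hedgehog genes 5 were lower (adjusted p = 0.00505 by camera and adjusted p = 0.351 with an estimated correlation), such as Notch1 (319 ± 153 against 3136) and Jag1. In all 4229 genes were called, 2070 higher and 2159 lower, but more higher than lower with quantile normalization (2109 and 1806), and 621 with close pairs counted as 1 sample, 201 higher and 420 lower. The rule named Arhgef5 (1932 ± 767 against 0, at least 665-fold higher), Arhgap36, Hist1h2ao, Adcy8 and Tmtc2 as higher, and Lect1, Eln, Lcn2, Hapln1 and Sfrp2 as lower. Of the genes called here, 1043 higher and 1118 lower ones were also called the same way between G34W K36R and G34W, which share no library with these groups (298 and 350 in independent lists, means of 30.6 and 33.65 in the simulation with shared cultures; covariance of the fold changes 1.17, at most 0.0236 in that simulation). The simulated lists were shorter here (means of 414 and 1282 calls, against 4229 and 3882), so their counts of shared genes are not comparable. Nor are the covariances, since genes varied independently in each simulated culture and none moved together.

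**Figure D3:**
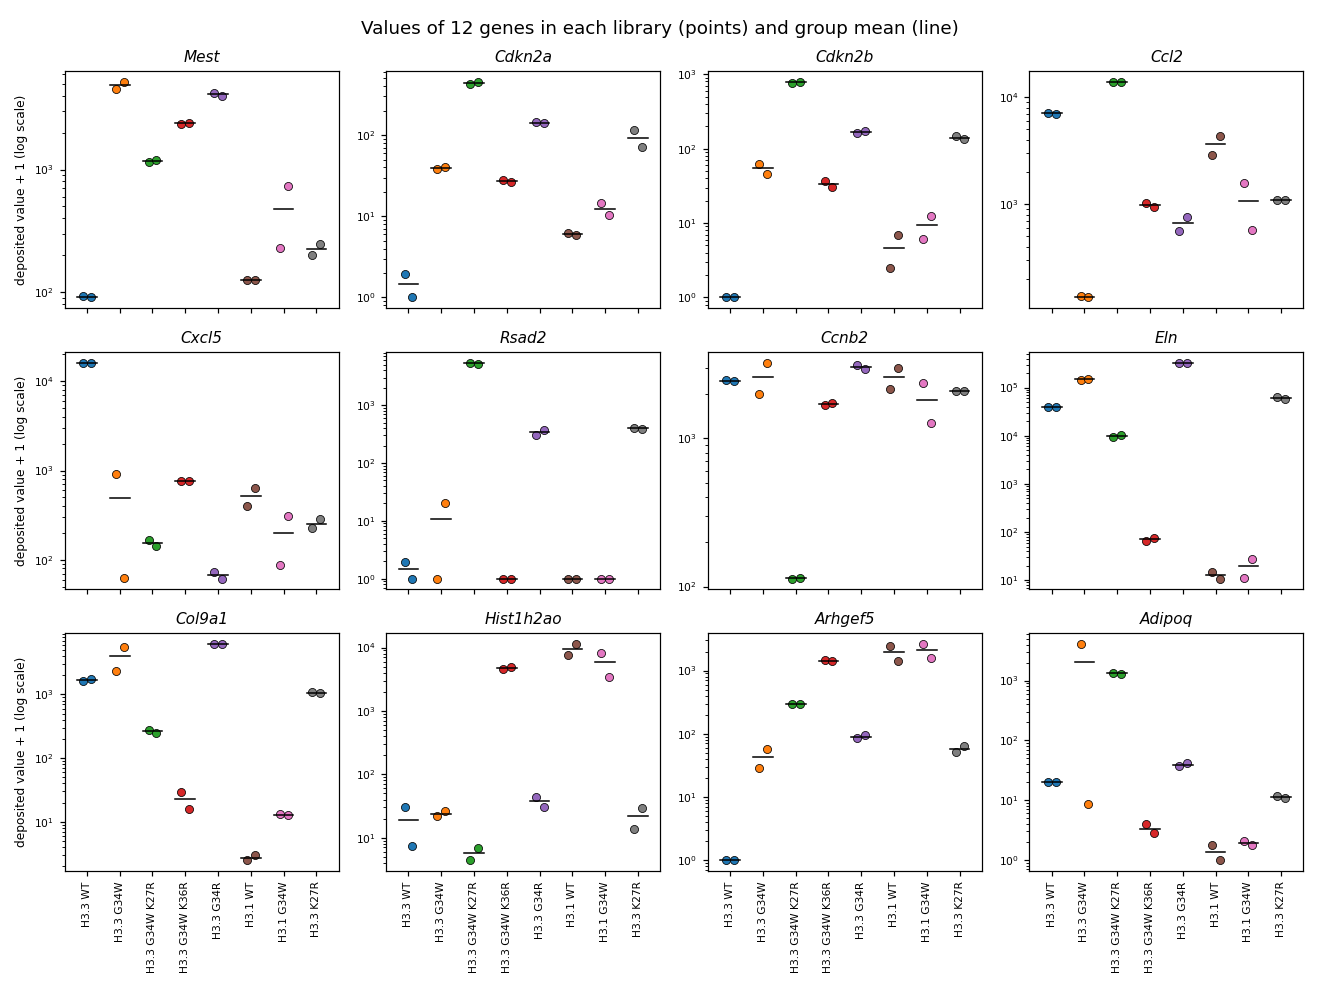
Deposited value plus 1, on a log scale, of 12 genes in each of the 16 libraries (points) with the mean of each group (line), the genes having been picked after their values were seen. Mest lies between 3995 and 5234 in G34W and G34R and at 89.1 to 92.0 in H3.3 wild type; Eln lies under 76 in the H3.1 groups and in G34W K36R.

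The interactions test the difference between effects. The interaction of G34W with K27R was called for 1007 genes. Where position 27 is arginine, 345 had a higher and 662 a lower log2 fold change of G34W. The count was below the mean of 1129 in the simulated data with no change and shared cultures. It was 3 with close pairs counted as 1 sample (Serpina3f, Ccl2 and Igfbp2). It was 1973 with the wild-type libraries counted separately, and 2091 and 1612 without H3.3 G34W replicates 1 and 2, 474 and 509 without H3.3 G34W K27R replicates 1 and 2, 1711 and 1707 without H3.1 G34W replicates 1 and 2 and 467 and 474 without H3.3 K27R replicates 1 and 2. The log2 fold change of G34W was lower in the K27R context for 29 of 30 G2 and M phase genes (median difference -3.74). Their median was 0.04 against wild type and -3.79 against K27R (adjusted p = 9.4e-28 by camera and adjusted p = 0.262 with an estimated correlation). It was also lower for 16 of 21 cholesterol synthesis genes, with medians of 0.98 and -1.89 (adjusted p = 5.4e-17 by camera and adjusted p = 0.262 with an estimated correlation). It was higher for 20 of 49 interferon-stimulated genes, with medians of -0.30 and 2.48 (adjusted p = 8.1e-25 by camera and adjusted p = 0.207 with an estimated correlation). The interaction of G34W with the histone type was called for 25 genes (simulated mean 405) and for 0 with close pairs counted as 1 sample. Of the 25, 14 had a higher and 11 a lower log2 fold change in H3.3 (20 and 25 with quantile normalization). These 11 were all called lower in H3.3 G34W against wild type, so lower does not mean a weaker effect. Among the 25 genes were Mest (log2 fold change 4.05 ± 0.63, adjusted p = 0.0491), Serpina3g (log2 fold change -8.95 ± 0.81, adjusted p = 0.00259) and Cdkn2a. That count was 175 with the wild-type libraries counted separately, and 12 without H3.3 wild type replicate 1, 138 and 796 without H3.3 G34W replicates 1 and 2, 3 and 3 without H3.3 G34W K27R replicates 1 and 2, 3 and 3 without H3.3 G34W K36R replicates 1 and 2, 7 and 7 without H3.3 G34R replicates 1 and 2, 907 and 15 without H3.1 wild type replicates 1 and 2, 854 without H3.1 G34W replicate 1 and 4 and 4 without H3.3 K27R replicates 1 and 2.

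The genes fixed for report whatever their result behaved as follows over the 13 tests. H3f3a, Eed, Setd2, Runx2 and Pparg passed in none. Ezh2 was lower in G34W K27R against wild type (862 ± 56.2 against 2017) and against K27R, and higher in H3.1 than in H3.3 wild type (3697 ± 163 against 2017), as was Suz12 (7225 ± 724 against 2539). The 12 PRC2 subunits gave no list call in any of the 13 tests; between H3.3 G34W and wild type their median log2 fold change was -0.24 (adjusted p = 0.133 by camera and adjusted p = 0.466 with an estimated correlation). H3f3b was lower in G34W K27R than in G34W (log2 fold change -0.78 ± 0.16) and K27R (log2 fold change -0.62 ± 0.16). Alpl, an alkaline phosphatase of bone cells, was lower in both double mutants against G34W and wild type, with 4.51 ± 3.25 against 76.7 ± 27.6 in G34W K27R against G34W, and was at 0 in the 4 H3.1 libraries. Sox9 was lower in G34W K36R against G34W (log2 fold change -0.69 ± 0.15) and wild type and higher in G34W K27R than in K27R (log2 fold change 0.94 ± 0.15). Col1a1 was lower in G34W K27R than in K27R (log2 fold change -1.76 ± 0.50). Igf2 passed in both double mutants against wild type, and in H3.3 G34W was at 731 ± 734 with an adjusted p of 0.0964. Mycn was 0 in all 16 libraries, which allows up to 3 reads in each, Tnfsf11 was at most 1.88, and Sp7, at most 7.07, lay below the minimum mean. H19 was not analysed here.

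**Figure D4:**
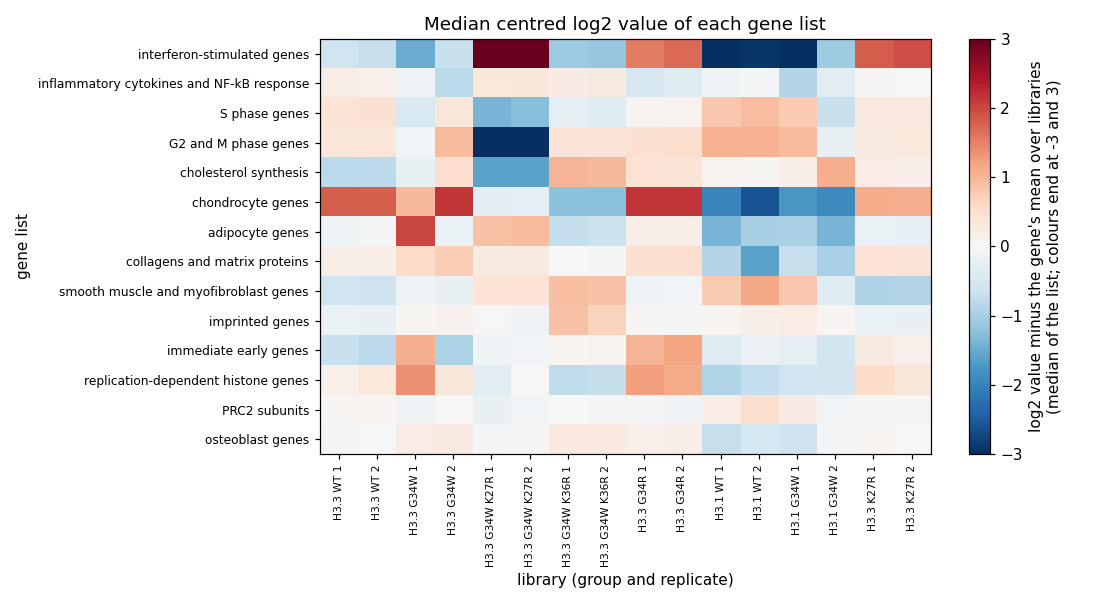
Median over the members of 14 gene lists of the log2 value minus the gene's mean over all libraries, for each library; the lists drawn were picked after their values were seen, and colours end at -3 and 3. Interferon-stimulated genes lie at 4.68 and 4.73 in G34W K27R and at 1.54 to 1.94 in G34R and K27R, and G2 and M phase genes at -3.45 in both libraries of G34W K27R.

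The deposited subset of 180 genes holds 148 of the genes tested here. Of these 107 were higher and 36 lower in both G34W and G34R against wild type, and 5 were split. The authors chose these genes on these samples by a rule that is not stated, so their direction is no independent evidence. In H3.1 G34W against H3.1 wild type the 107 genes had a median log2 fold change of 0.03 and the 36 genes one of -0.34. Between G34R and K27R the medians were 1.54 and -2.28, and in G34W K27R against K27R they were -0.50 and 0.01.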

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

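These results passed a test of the difference between 2 effects of G34W. The tests of explanations below were chosen after the results were seen. The test at equal depth replaced an earlier depth test that had not decided, and its own count had not been seen when it was set. The tests of the type of histone and of the share of cells also replaced earlier ones, after the values were seen. Neither count of genes was above its mean in simulated data with no change by group in which close pairs shared a culture (1129 and 405), so these calls cannot be set apart from differences between single cultures. The interaction of G34W with K27R was called for 1007 genes, 345 with a higher and 662 with a lower log2 fold change beside K27R. Differences in log2 fold change were higher for Serpina3f (11.08), Ccl2 (9.37), Ccl7 (7.04), Sprr1a (6.71), Gpr176 (6.19), Gbp5 (6.04) and Sox9 (0.92). They were lower for Igfbp2 (-11.78), Scg2 (-9.19), Lcp1 (-8.60), Stmn2 (-8.19), Fxyd6 (-8.13), Matn3 (-7.68), H3f3b (-1.24) and Alpl (-5.46). In 10 more genes at least 1 of the 4 groups held 3 or fewer reads, so the fitted difference depends on the pseudocount and is no bound. These were Prl2c3 (6.73), Siglecg (6.72), Csmd1 (6.29) and Cxcl11 (5.94) on the higher side and Gli1 (-8.60), Serpina1e (-8.45), Klhl30 (-7.72), Hoxb9 (-7.61), Cdkn2a (-2.44) and Cdkn2b (-3.28) on the lower. With each of the 5 close pairs counted as 1 sample Serpina3f, Ccl2 and Igfbp2 were called, 3 genes in all.

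The interaction of G34W with the histone type was called for 25 genes, 14 with a higher and 11 with a lower log2 fold change in H3.3 (20 and 25 with quantile normalization). Differences were higher for Igfbp2 (4.58), Mest (4.05), Hey1 (2.54) and Chst11 (1.71), and lower for Serpina3g (-8.95), Serpina3f (-7.12), Tmem176a (-5.08), Mt2 (-4.74), Tmem176b (-4.03), Ccl2 (-3.80), Ankrd33b (-3.45), Nckap5 (-2.91) and Aim2 (-2.16). In 7 more genes a group held 3 or fewer reads and the fitted difference is no bound: Arhgef5 (5.19), Podxl2 (4.77), Cdkn2b (4.66), Bmx (4.27), Dusp27 (4.25) and Cdkn2a (3.73) on the higher side and Serpina3i (-9.25) on the lower. None of the 25 was called with close pairs counted as 1 sample.

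The 150 genes called between H3.3 G34W and wild type were weighed against the state of the wild-type culture and the closeness of the pairs. A wild-type culture that stands apart would leave these genes unmoved between G34R and K27R, which share no library with the comparison. There the median log2 fold change in the direction of G34W was 0.83, outside the -0.09 to 0.09 of the central 95% of random lists, with 124 of 150 in that direction. These genes thus also differed between groups other than wild type. The random lists were drawn gene by gene, so they do not show how far genes that vary together move between single cultures. The close pairs of G34R and K27R may each come from a single culture. The value therefore cannot decide on the wild-type culture as the whole cause. Near-identical pairs that make the spread look too small remain a candidate explanation for the calls: with these counted as 1 sample 0 genes were called, while in simulated data 2-fold changes were recovered at 13.7% against 33.0% and 4-fold changes at 71.8% against 78.8%. All libraries of those simulated data varied independently, unlike the close pairs here. How much of the loss of calls is lost power therefore cannot be told. An effect of G34W, as the design names it, stays open beside these explanations.

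H3.3 G34W K36R lay nearer to the H3.1 libraries than to H3.3 G34W, with a correlation across genes of 0.955 with H3.1 wild type and 0.911 with H3.3 G34W. A first depth test, the median absolute log2 fold change of 0.951 over 2098 called genes with a mean of at least 1000, fell between its bounds. In the test that replaced it the reads of every library were drawn down to 26.02 M. Then 4148 genes were called between H3.1 and H3.3 wild type, against 4229 at full depth. Between G34W K36R and H3.3 G34W there were 3766, against 3882. These counts hardly depended on depth. The first of them holds no G34W K36R library, and the correlations were not computed at equal depth. A part of depth in the place of G34W K36R was therefore not tested. In a first test of the type of histone 55.5% of those 4229 genes lay nearer to H3.1 wild type in G34W K36R, between its bounds, against 9.48% to 25.3% in the other H3.3 mutants and 87.1% in H3.1 G34W. Were the type alone the cause, these genes would be unmoved between G34W K36R and H3.3 G34W, which both carry H3.3 and share no library with the wild types. There the median log2 fold change in the direction of H3.1 was 0.65, outside the 0.02 to 0.07 of the central 95% of random lists, with 3823 of 4229 in that direction. By the same median each G34W K36R library stood 0.40 to 0.74 above each library of the other H3.3 mutants, and these at most 0.33 above each other. These values restate in genes that G34W K36R lies toward the H3.1 libraries, so they are no separate test. By design G34W K36R carries H3.3, so the type of histone alone cannot account for its place. A shared culture or library batch cannot be told apart from the groups, since the labels give no batch, and an effect of the K36R change itself was not tested.

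Cdkn2a and Cdkn2b were near 0 in H3.3 wild type, at 1.52 to 5.86 in the H3.1 wild-type libraries, 5.18 to 13.5 in those of H3.1 G34W and 25.6 to 797 in those of the H3.3 mutants, so low values were not particular to H3.3 wild type. At the level of H3.3 G34W the 2 wild-type libraries would hold 189.7 reads of both genes, and they held 1 (95% interval 0.025 to 5.57), so depth is argued against. Mtap, a neighbour of both genes on chromosome 4 in GRCm38, stood at 67.0% of its mean in the other groups, which argues against the complete loss of a segment that includes it; a loss of Cdkn2a and Cdkn2b alone stays open. A differing share of cells that express both genes could not be settled: the ratio of their reads differed beyond counting error between 7 groups of 20 to 2357 reads (chi-square p = 3.8e-05) and between the 5 with at least 100 reads (p = 3.0e-04), but against the spread between libraries of a group p was 0.0842 and 0.0660 (F test), and the 1 read in wild type gives no ratio there. A response to the transgenes stays open as untested.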

How the results depend on the processing

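Every alternative kept the direction of each of the 230 reported named values that were called and tested, and the cause of a change below was not tested unless stated. Pseudocounts of 0.5 and 5, a minimum mean of 50 and the TMM rescaling moved no count of genes by over 1.5 times. The averaging of the wild-type libraries was chosen after the data were seen, and their separate count below is the one of the design. The close pairs counted as 1 were added after the data were seen. Counts that moved were, with no filter on low values, 4 for H3.1 G34W against H3.1 wild type and 16 for the interaction of G34W with the histone type. With quantile normalization they were 260 for G34W against wild type, 545 for G34R against wild type and 45 for the interaction of G34W with the histone type. With eBayes without trend and robust they were 3 for H3.1 G34W against H3.1 wild type and 45 for the interaction of G34W with the histone type. In fits of the compared groups alone, they were 0 for G34W against wild type, 7687 for G34R against wild type, 7019 for K27R against wild type, 839 for G34W K27R against G34W, 1369 for G34W K36R against G34W, 8496 for G34W K27R against wild type, 9566 for G34W K36R against wild type, 9664 for G34W K27R against K27R, 0 for G34R against G34W, 1332 for H3.1 against H3.3 wild type and 0 for the interaction of G34W with the histone type. With both wild-type libraries counted separately they were 956 for G34W against wild type, 1313 for G34R against wild type, 4 for H3.1 G34W against H3.1 wild type, 1124 for K27R against wild type, 3499 for G34W K27R against wild type, 4256 for G34W K36R against wild type, 1973 for the interaction of G34W with K27R and 175 for the interaction of G34W with the histone type. With each of the 5 close pairs counted as 1 sample (3 residual degrees of freedom, against 7) they were 0 for G34W against wild type, 0 for G34R against wild type, 0 for K27R against wild type, 347 for G34W K27R against G34W, 132 for G34W K36R against G34W, 141 for G34W K27R against wild type, 27 for G34W K36R against wild type, 0 for G34W K27R against K27R, 0 for G34R against G34W, 621 for H3.1 against H3.3 wild type, 3 for the interaction of G34W with K27R and 0 for the interaction of G34W with the histone type. The replicate block gave 82 for G34W against wild type, 265 for G34R against wild type, 0 for H3.1 G34W against H3.1 wild type, 309 for K27R against wild type, 2546 for G34W K27R against G34W, 3584 for G34W K36R against G34W, 1628 for G34W K27R against wild type, 1918 for G34W K36R against wild type, 3057 for G34W K27R against K27R, 93 for G34R against G34W, 3895 for H3.1 against H3.3 wild type, 845 for the interaction of G34W with K27R, 6 for the interaction of G34W with the histone type.

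Without 1 library, where a lone library is assumed to vary like the other groups, the counts ran from 50 to 1526 for G34W against wild type, from 75 to 987 for G34R against wild type, from 0 to 2477 for H3.1 G34W against H3.1 wild type, from 101 to 882 for K27R against wild type, from 1305 to 3507 for G34W K27R against G34W, from 1645 to 4884 for G34W K36R against G34W, from 892 to 2888 for G34W K27R against wild type, from 806 to 3320 for G34W K36R against wild type, from 1448 to 4427 for G34W K27R against K27R, from 3 to 1065 for G34R against G34W, from 3510 to 5417 for H3.1 against H3.3 wild type, from 467 to 2091 for the interaction of G34W with K27R, from 3 to 907 for the interaction of G34W with the histone type. Of the 230 called named values 62 remained called with close pairs counted as 1 sample and 205 with the block. Among genes not called in the main setting, Pparg turned sign and was called on leaving out a library of H3.3 G34W. Its log2 fold change without replicate 1 or 2 of H3.3 G34W was 0.998 or -1.03 in G34W K36R against G34W. It was 0.68 or -1.35 in G34R against G34W and 1.12 or -0.92 in G34W K27R against G34W, the turned sign being 0.998, 0.68 and -0.92. Nsd1 turned to -0.57 without H3.1 wild type replicate 1 in H3.1 against H3.3 wild type, and was at 0.64 without replicate 2. A further 76 sign changes concern values called in neither setting. Of 130 list calls 2 hold with an estimated correlation, 63 with fry, 114 with quantile normalization, 129 with TMM, 129 with close pairs counted as 1 and 130 with the block. Camera at a preset correlation compares genes with genes and depends little on the spread between samples. The counts with close pairs and with the block therefore say little on stability. For G34W against wild type 14 lists were called, and 16 with close pairs counted as 1, where no gene was called. All 150 alternative medians of the G34W genes moved by less than the median absolute deviation of fold changes between genes of the list. That bound is wide, and a median near 0 can change sign within it, so it says little on stability. With close pairs counted as 1, and with the compared groups alone, no gene was called, so these gave no median. The 2 planned count-model tests were not run, since the values are not whole reads. Depth limits genes near the floor of 3 reads, such as those at 0 in wild type.

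Beyond the scalings given beside the counts, the side with more genes, higher or lower, turned for H3.1 against H3.3 wild type with a minimum mean of 50 (1955 higher and 1841 lower) and without H3.1 wild type replicate 2 (2253 and 2230). It also turned for G34W K36R against wild type without H3.1 wild type replicate 1 or 2 (1667 and 1635, 1668 and 1632) and for G34R against G34W without H3.3 G34W replicate 2 (520 and 545). In fits of the compared groups alone it turned for G34R and K27R against wild type, G34W K36R against G34W and G34W K27R against K27R, and with close pairs counted as 1 for the interaction with K27R. For the interaction with the histone type it turned with a pseudocount of 5, no filter, the block and several libraries left out.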

Other observations

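Of the other lists, the 6 endothelial markers were lower in G34W K27R than in K27R for 3 members (adjusted p = 0.0354 by camera and adjusted p = 0.473 with an estimated correlation). Of 14 Notch and Hedgehog genes 5 were lower in G34W K36R than in G34W without a list call (adjusted p = 0.121 by camera and adjusted p = 0.621 with an estimated correlation). Integrated stress and unfolded protein response genes went both ways in G34W K36R against G34W, with 13 of 26 higher and 3 lower (adjusted p = 0.0130 by camera and adjusted p = 0.758 with an estimated correlation): Chac1 was at 3742 ± 18.2 against 863 ± 391 and Sdf2l1 at 371 ± 23.8 against 1449 ± 369. Of 21 p53 targets Zmat3 and Eda2r fell in G34R against wild type (adjusted p = 0.0357 by camera and adjusted p = 0.200 with an estimated correlation). The 40 developmental transcription factors known as Polycomb targets had a median log2 fold change of 0.20 in G34W against wild type with no member called (adjusted p = 0.0152 by camera and adjusted p = 0.358 with an estimated correlation), and 3 when adjusted over the list alone.

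Hist1h2ao was, in polyadenylated RNA, at 9547 in H3.1 wild type and 4733 in G34W K36R, against 17.9 in H3.3 wild type. Igf2 was at 1250 and 212 in the 2 H3.3 G34W libraries, which also differed in Adipoq (4082 and 7.65).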
